A study of Mus musculus with 15 samples.

How the data were processed

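RNA was sequenced from heart tissue that held the infarcted and the surrounding muscle, from male C57BL/6 mice of 8 to 10 weeks. Per the labels, polyA RNA was purified from 500 ng of total RNA and made into libraries with a kit that marks the strand. The labels list 15 samples in 5 groups, named sham, untreated, rivaroxaban (a factor Xa inhibitor), dabigatran (a factor IIa, or thrombin, inhibitor) and activated protein C (aPC). One table of the whole series was analysed, and it holds 11 of these libraries: sham replicates 003, 006 and 007, untreated replicates 17 and 19, rivaroxaban replicates Riva-313 and Riva-319, dabigatran replicates Dabi-202 and Dabi-204, and aPC replicates aPC-791 and aPC-792, where the full names are those of the labels. The remaining 4 samples were not analysed here. The labels tie each library to its own number but describe the surgery once for the whole study, so the untreated group is used under the name its label gives it. No label gives a batch, a day or a pairing, and no replicate number is shared between groups.

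The deposited table gives log2 CPM normalized by the trimmed mean of M values (TMM), as its file name states. Per the submitters' processing notes, bcl2fastq, FastQC, Trim Galore, STAR and edgeR were used, with genome build mm10 and no versions. The counter, the annotation release, the strand setting and any filter on genes are not given in the sources used here. Each antisense or overlapping gene is therefore uncertain, because reads of a gene and of its partner could be mixed.

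The lowest value was -3.93 in every one of the 11 libraries. When the log2 values of the authors were turned back to CPM and that lowest value was taken off, 100% of the values in every library were whole multiples of 1 step, to within 0.05 of a read. The step gives the number of reads on listed genes, which ran from 26203566 in dabigatran replicate Dabi-202 to 36135006 in dabigatran replicate Dabi-204. A gene with 3 reads lies between -2.83 and -2.41 log2 CPM, and a fold change near that level is understated because about 2 reads had been added before the log. Standard errors and intervals come from the spread between libraries in the fit.

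Gene symbols are those of the deposited table. Of its 16658 identifiers, 16654 were matched to GENCODE release M21, which supplied GC content, length, position on mm10 and gene type, and 16639 symbols were equal. A gene was tested when its value was at least 0 in at least 3 libraries, which left 13541 genes.

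The main test was two-sided limma-trend on the log2 values, in 1 fit of the 5 group means over the 11 libraries (15 were planned). All groups share an estimate of the spread, mostly low for the untreated pair, so errors and p against untreated run small. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes of a comparison. The analysis used R 4.3.3, limma 3.58.1 and statmod 1.5.0. Groups, comparisons, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The procedure was tested on simulated data with 100 genes changed by 2-fold and 100 by 4-fold among the 13541. It recovered from 47 (aPC against untreated) to 68 (untreated against sham) of the former and from 90 (aPC against rivaroxaban) to 100 (aPC against dabigatran) of the latter.

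Genes were named by a fixed rule. It takes the 6 largest rises and the 6 largest falls among called genes whose libraries do not overlap between the groups and whose mean is at least 1 on the log2 scale, leaving out predicted genes. It adds up to 4 members with the smallest p of each list described, and a fixed set of inflammation, cardiac stress and coagulation genes. Where no gene passed, it takes the 3 genes per direction with the smallest p. Some genes that the rule takes are not reported here. Genes named outside this rule are said to be so. For a pair of groups with 2 libraries each, chance alone keeps the libraries of a gene apart in 33% of genes, and for 2 against 3 in 20%.

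Gene lists for cell types, signalling and metabolism, 30 in number, were tested with limma's camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 27 lists with at least 5 tested members. Camera with an estimated correlation and limma's fry were the alternatives. Each list also has the count of called members over all genes tested and the count adjusted over the list alone.

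An injury score per library is the mean of the signature genes that were higher minus the mean of those that were lower in the contrast of the other 4 groups with sham. Scores were compared by two-sided exact permutation tests. With 2 libraries against 2 these cannot give a p under 0.333. The similarity of drug responses is the covariance across tested genes of the fold changes against untreated, beside the value simulated for unchanged groups that share the untreated libraries.

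Alternatives fixed in advance were no filter and a stricter filter of 2 log2 CPM, 1 CPM added before the log, quantile normalization, centring of each library on its median, eBayes without the trend and with the robust option, library weights, a fit of only the 2 groups compared, an absolute log2 fold change of at least 1, an adjusted p under 0.1, and leaving out each library in turn. The count tests foreseen for recovered reads were not run, and voom took their place. Added after seeing the data were limma's voom on the recovered reads, removal of a trend over GC content and length from each library, removal of the 20 most abundant genes with each library rescaled to its remaining reads and without the TMM factors, a fit without the untreated libraries, drug responses computed with 1 untreated library each, and an enrichment of the gene ontology terms that the deposited table gives for each gene (one-sided hypergeometric test among the tested genes that have a term).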

Results

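Messenger RNA of the heart was measured in 11 libraries: 3 sham, 2 untreated, 2 rivaroxaban, 2 dabigatran and 2 activated protein C (aPC). Per the labels, mice received rivaroxaban at 3 mg/kg or dabigatran at 10 mg/kg for 7 days, or aPC at 1 mg/kg 30 min before surgery. The left anterior descending artery was tied for 90 min, reperfusion lasted 24 h, and drugs were given again from 2 h after surgery. Reads on listed genes numbered 28254641 and 26629925 in the aPC libraries and 31827652 and 31170553 in the untreated. They numbered 26203566 and 36135006 in the dabigatran, 27072182 and 32108787 in the rivaroxaban, and 31774727, 32771278 and 29122886 in the sham libraries. All values are log2 CPM (reads of a gene scaled to the size of its library). A value after ± is limma's standard error of a log2 fold change (mostly low against untreated) unless SD is named, and n is 2 per group, 3 in sham.

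Set against the counting error of reads alone, replicates of the same group had a chi-square per gene from 25.7 (rivaroxaban) to 126 (untreated). The untreated libraries stood furthest apart, with a Spearman correlation of 0.955 and an SD of the log2 difference of 0.792, against 0.313 to 0.483 in every other pair of the same group. The aPC libraries differed in another way: Gm42418, a gene known to overlap ribosomal RNA sequence, took 6.78% and 6.73% of their reads and between 0.997% and 2.09% in the other 9. A first principal component over the tested genes held 39% of the variance and a second 25.2%.

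**Figure D1:**
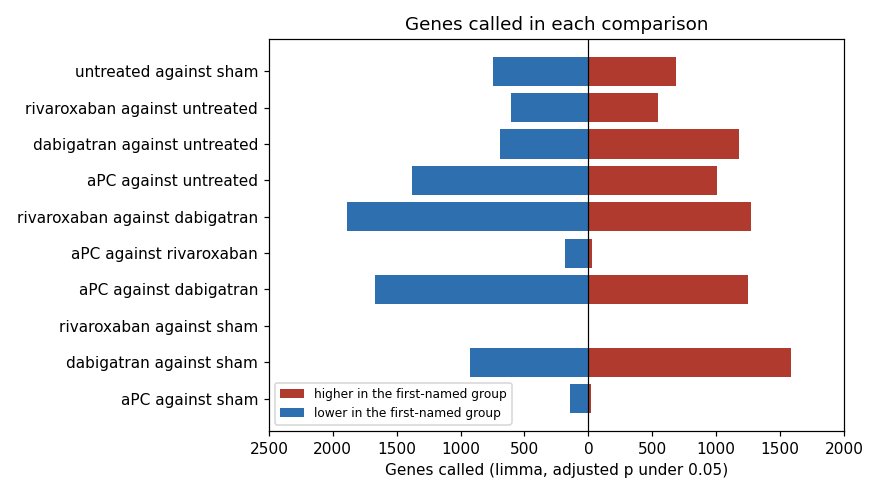
Bars show how many of 13541 tested genes were called higher (to the right) or lower (to the left) by limma at an adjusted p under 0.05, for each of the 10 comparisons, with the first-named group relative to the second. Rivaroxaban against dabigatran gave 3161 genes and rivaroxaban against sham gave 0.

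The comparison of untreated with sham hearts asks what the labelled untreated state changed. At camera's preset correlation, neutrophil markers (10 of 14 called) and oxidative stress genes (6 of 12) were higher in untreated hearts and resident macrophage markers (10 of 15) lower, while 0 lists passed with an estimated correlation. Without sham replicates 003, 006 and 007 and untreated replicate 19 the oxidative stress count was 3, 1, 1 and 3, and the neutrophil count 2, 1, 4 and 2. Inhbb, the beta B subunit of inhibin and activin, rose by 4.61 ± 0.37 (adjusted p = 0.000246), from 2.30 ± 0.08 (SD, n = 3) in sham to 6.91 ± 1.09 (SD, n = 2) in untreated hearts. Grk5, a kinase of G protein-coupled receptors, rose by 3.34 ± 0.26 (adjusted p = 0.000234), and AA467197 by 3.50 ± 0.39, Sphk1 (sphingosine kinase) by 3.67 ± 0.69, the activity-regulated gene Arc by 3.60 ± 0.74 and the neutrophil gene Retnlg by 3.29 ± 0.79. The largest falls were in Fcrls (-3.43 ± 0.40), the apelin receptor Aplnr (-3.42 ± 0.45), the myeloid lectin receptor Clec12a (-3.09 ± 0.39), the Nogo receptor Rtn4r (-3.05 ± 0.34), the matrix protein gene Cilp (-2.98 ± 0.51) and Stmn2 (-2.86 ± 0.34). In all, 1435 genes were called, 687 higher and 748 lower, with 4325 at an unadjusted p under 0.05.

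Among neutrophil markers, 10 of 14 tested members rose and 0 fell (12 over the list alone, camera adjusted p = 4.48e-07, or 0.619 with an estimated correlation). Examples are the interleukin 1 decoy receptor Il1r2 at 3.29 ± 0.64, Trem1 at 2.38 ± 0.53 and Mmp9 at 1.47 ± 0.34, and the calprotectin gene S100a8 rose by 2.04 ± 0.50 (adjusted p = 0.0319). Resident macrophage markers moved the other way: 10 of 15 fell (10 over the list alone, camera adjusted p = 4.48e-07, or 0.619 with an estimated correlation), among them Cbr2 at -2.16 ± 0.17, Vsig4 at -2.46 ± 0.28, the colony-stimulating factor receptor Csf1r at -1.27 ± 0.17 and Adgre1, which encodes F4/80, at -1.74 ± 0.25. Of the nuclear factor kappa B targets, 5 of 16 rose (6 over the list alone, camera adjusted p = 0.000533, or 0.619 with an estimated correlation). Nfkbia stood at 1.63 ± 0.21 and Tnfaip3, both feedback inhibitors of the pathway, at 1.73 ± 0.29. Oxidative stress genes rose in 6 of 12 (8 over the list alone, camera adjusted p = 0.000109, or 0.619 with an estimated correlation). The thioredoxin reductase Txnrd1 stood at 1.41 ± 0.24 and the glutathione synthesis gene Gclc at 1.36 ± 0.29. Immediate-early genes rose in 5 of 19 (6 over the list alone, camera adjusted p = 0.00178, or 0.757 with an estimated correlation). Myc stood at 2.19 ± 0.33 and Fosl1 at 1.32 ± 0.28. Called immediate-early genes numbered 1 without sham replicate 003, sham replicate 006 or untreated replicate 19, and 3 without Riva-313 or Riva-319. Called nuclear factor kappa B targets numbered 3 without sham replicates 003 or 006, and 7 higher and 1 lower without untreated replicate 17. The neutrophil and oxidative stress counts were given above.

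Chemokines were mixed: Cxcl1, Cxcl2 and Cxcl3, which draw neutrophils, rose by 2.10 ± 0.50, 2.52 ± 0.45 and 2.62 ± 0.61, while Cxcl12 fell by 1.30 ± 0.14. The list's median was -0.06, or 0.04 after quantile normalization, its mean 0.49, and its camera test pointed upward (adjusted p = 0.544). Matrix and fibrosis genes had 3 members higher and 6 lower of 16 (camera adjusted p = 0.0623), with the collagen gene Col5a1 at -1.85 ± 0.33, Col1a1 at -1.89 ± 0.39 and the platelet and matrix protein gene Thbs1 at 2.19 ± 0.39. Smooth muscle and pericyte markers fell in 3 of 10 (8 over the list alone, camera adjusted p = 0.00178, or 0.619 with an estimated correlation). Smooth muscle myosin Myh11 stood at -0.94 ± 0.23 and calponin Cnn1 at -1.86 ± 0.45. Of the coagulation, fibrinolysis and protease-activated receptor genes, 3 rose and 3 fell of 20. The urokinase receptor Plaur rose by 2.69 ± 0.34 and the thrombin receptor F2r by 0.69 ± 0.18. Tissue factor F3 fell by 0.88 ± 0.23 and von Willebrand factor Vwf by 0.66 ± 0.13. Interleukin 6, at 2.31 ± 0.69 (adjusted p = 0.0576), and the natriuretic peptides Nppa, at 0.13 ± 0.34 (adjusted p = 0.821), and Nppb, at -0.45 ± 0.97 (adjusted p = 0.781), did not pass. The count was 5197 without untreated replicate 17, 703 without untreated replicate 19, 862 and 865 without Riva-313 and Riva-319, and 447, 261 and 710 without sham replicates 003, 006 and 007. Smooth muscle markers had 0 called by limma without any single sham replicate, 5 without Dabi-202 or Dabi-204 and 6 without untreated replicate 19. Coagulation genes had 1 higher and 0 lower without sham replicates 003 or 006, 1 and 2 without sham replicate 007, 1 and 1 without Riva-313 or Riva-319, and 7 and 3 without untreated replicate 17. Chemokines had 1 and 0 higher without sham replicates 003 and 006, and 4 higher and 3 lower without untreated replicate 17, and matrix genes 2 higher and 2 lower without sham replicate 006 or untreated replicate 19. Of the 39 genes named for this comparison as called, 25, 21, 29 and 27 were called without sham replicates 003, 006 and 007 and untreated replicate 19. Library weights, which were 0.242 for each untreated library, left 25 genes, and a fit of only these groups gave 471.

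Rivaroxaban against untreated asks what the factor Xa inhibitor changed relative to no drug. Neutrophil markers (11 of 14 called) and nuclear factor kappa B targets (9 of 16) were lower with rivaroxaban at camera's preset correlation, while 0 lists passed with an estimated correlation or by fry. Without Riva-313 those counts were 0 and 1, without Riva-319 4 and 2, and without untreated replicate 19 the neutrophil count was 3. Cxcl3 and Cxcl2 fell by 4.12 ± 0.67 and 4.09 ± 0.49 (adjusted p = 0.00865 and 0.00289), Inhbb by 4.85 ± 0.41, the aggrecan-cleaving protease gene Adamts4 by 4.56 ± 0.36 and Sphk1 by 4.01 ± 0.76. Interleukin 6 (Il6) fell by 3.22 ± 0.76 (adjusted p = 0.0305), interleukin 1 beta (Il1b) by 1.67 ± 0.45 (adjusted p = 0.0452) and S100a8 by 2.62 ± 0.55 (adjusted p = 0.0228). The largest rises were in Derl3, of protein degradation at the endoplasmic reticulum (4.43 ± 0.90), Stum (3.43 ± 0.41), the methyltransferase gene Inmt (3.41 ± 0.61), Clec12a (3.14 ± 0.43), AU021092 (3.11 ± 0.34) and Stmn2 (3.02 ± 0.37). Of 1147 called genes, 544 were higher and 603 lower, with 3997 at an unadjusted p under 0.05.

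Neutrophil markers fell in 11 of 14 (12 over the list alone, camera adjusted p = 4.74e-09, or 0.58 with an estimated correlation). S100a9 stood at -2.97 ± 0.57, Trem1 at -2.84 ± 0.58 and Il1r2 at -3.40 ± 0.70. Nuclear factor kappa B targets fell in 9 of 16 (10 over the list alone, camera adjusted p = 1.55e-06, or 0.58 with an estimated correlation), among them the endothelial adhesion molecule Sele at -2.62 ± 0.32 and Tnfaip3 at -1.84 ± 0.32, while Tnf itself stood at -1.13 ± 0.56 (adjusted p = 0.205). Of 13 chemokines 4 fell and 1 rose, with Cxcl1 at -2.97 ± 0.55 and Cxcl12 at 0.96 ± 0.15 (7 lower and 1 higher over the list alone, camera adjusted p = 0.0666). Immediate-early genes fell in 6 of 19 (10 over the list alone, camera adjusted p = 1.91e-05, or 0.58 with an estimated correlation). Junb stood at -1.58 ± 0.30 and Egr2 at -2.06 ± 0.40. Oxidative stress genes fell in 4 of 12 (8 over the list alone, camera adjusted p = 0.000242, or 0.58 with an estimated correlation). Txnrd1 stood at -1.80 ± 0.26 and glutathione reductase Gsr at -0.93 ± 0.18. Without Riva-313 and Riva-319 the called genes numbered 0 and 4 for neutrophil markers, 1 and 2 for nuclear factor kappa B targets, 0 and 1 for immediate-early genes, 0 and 2 for oxidative stress genes, and 1 and 2 for chemokines, all lower. Without untreated replicate 19 they were 3 for neutrophil markers and 3 for immediate-early genes. Oxidative stress genes had 2 called without any single sham replicate and 8 without untreated replicate 17, where chemokines had 6 lower and 2 higher.

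Resident macrophage markers rose in 4 of 15 (9 over the list alone, camera adjusted p = 0.00375, or 0.58 with an estimated correlation). Cbr2 stood at 1.51 ± 0.19, Vsig4 at 1.88 ± 0.31, Csf1r at 0.83 ± 0.18 and Adgre1 at 1.15 ± 0.27. Smooth muscle and pericyte markers rose in 4 of 10 (6 over the list alone, camera adjusted p = 0.00367, or 0.58 with an estimated correlation). Myh11 stood at 1.08 ± 0.25 and Rgs5 at 0.59 ± 0.14. Matrix genes had 3 higher and 3 lower of 16, with Col3a1 at 2.54 ± 0.55 and Thbs1 at -2.98 ± 0.43 and the crosslinking enzyme gene Lox at -2.31 ± 0.38. Plaur fell by 3.23 ± 0.37, F2r by 0.86 ± 0.19 and the tissue plasminogen activator Plat by 0.81 ± 0.22. The count was 43 and 112 without Riva-313 and Riva-319, 5029 and 651 without untreated replicates 17 and 19, and 685 and 698 without sham replicates 003 and 006. Smooth muscle markers had 0 called by limma without Riva-313, Riva-319 or sham replicate 006, 1 without sham replicate 003, and 2 without sham replicate 007, aPC-791 or aPC-792. Resident macrophage markers had 0 and 1 called without Riva-313 and Riva-319, 2 without untreated replicate 19, and 7 higher and 1 lower without untreated replicate 17. Matrix genes had 0 higher without Riva-313, Riva-319 or untreated replicate 19, and 1, 2 and 3 lower. Of the 37 genes named for this comparison as called, 9 and 15 were called without the rivaroxaban replicates, and 26 without untreated replicate 19. Library weights left 37 genes. A limma fit of only these groups called 0, with 2287 genes at an unadjusted p under 0.05.

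Dabigatran against untreated asks the same of the thrombin inhibitor. Here 10 of 14 monocyte markers, 7 of 16 matrix genes and 6 of 10 cardiac stress genes were higher and 12 of 22 fatty acid oxidation genes lower. These lists passed at camera's preset correlation and 0 lists with an estimated correlation. Cardiac stress genes had 1 called without Dabi-202, 3 without sham replicate 003 and 2 without any other single library but Dabi-204 and untreated replicate 19. Monocyte markers had 5 without Dabi-202, matrix genes 2 without Dabi-204, and fatty acid oxidation genes 4, 2 and 2 without Dabi-202, Dabi-204 and untreated replicate 19. The osteopontin gene Spp1 rose by 4.30 ± 0.69 (adjusted p = 0.00403), from 3.67 ± 1.04 (SD, n = 2) to 7.97 ± 0.32 (SD, n = 2), and Derl3 by 5.29 ± 0.90, Clec12a by 4.86 ± 0.43, Sprr1a by 3.95 ± 0.76, Rasgrp4 by 3.82 ± 0.45 and tenascin C (Tnc) by 3.70 ± 0.67. The largest falls were in Tmem82 (-3.54 ± 0.59), the mitochondrial carrier Ucp3 (-3.20 ± 0.62), Serpina3f (-3.08 ± 0.67), Slc10a6 (-2.91 ± 0.68), Hif3a (-2.91 ± 0.56) and the peptidase gene Lvrn (-2.80 ± 0.44). Il1b rose by 2.72 ± 0.45 (adjusted p = 0.0044), Tnf by 1.95 ± 0.56 (adjusted p = 0.0442) and the atrial natriuretic peptide Nppa by 1.77 ± 0.37 (adjusted p = 0.0136). Of 1868 called genes, 1180 were higher and 688 lower, or 63.2% higher, with 4294 at an unadjusted p under 0.05. That share was 46.9% when libraries were centred on their median and 53.1% after quantile normalization, which moved the median fold change of all genes by up to 0.13 and 0.10 in any comparison.

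Monocyte and recruited macrophage markers rose in 10 of 14 (13 over the list alone, camera adjusted p = 1.25e-06, or 0.449 with an estimated correlation). The chemokine receptor Ccr2 stood at 3.40 ± 0.34 and Clec4n at 3.38 ± 0.50. Neutrophil markers rose in 6 of 14 (8 over the list alone and 1 lower, camera adjusted p = 0.00793, or 0.492 with an estimated correlation). Csf3r, the receptor of granulocyte colony-stimulating factor, stood at 3.26 ± 0.42, Mmp9 at 2.96 ± 0.37 and S100a8 at 2.60 ± 0.55. Resident macrophage markers rose in 8 of 15 (9 over the list alone, camera adjusted p = 0.000176, or 0.449 with an estimated correlation). Csf1r stood at 1.45 ± 0.18 and Adgre1 at 1.89 ± 0.27. B cell markers rose in 6 of 7 (6 over the list alone, camera adjusted p = 0.000478, or 0.449 with an estimated correlation). Cd37 stood at 1.99 ± 0.22 and Blk at 2.92 ± 0.52. Chemokines rose in 4 of 13 (5 over the list alone, camera adjusted p = 0.00653, or 0.449 with an estimated correlation). Ccl7 stood at 2.85 ± 0.29 and Ccl12, both of monocyte recruitment, at 2.73 ± 0.40. Monocyte markers had 5 called and neutrophil markers 2 higher and 1 lower without Dabi-202. B cell markers had 3 without Dabi-202, 2 without Dabi-204 and 3 without sham replicate 003, and resident macrophage markers 4 without Dabi-204. Nuclear factor kappa B targets had 3 higher and 1 lower of 16 (camera adjusted p = 0.0645, or 0.534 with an estimated correlation), with 1 higher without Dabi-202 and 8 higher without untreated replicate 17. Acute phase and complement genes had 2 higher and 2 lower of 12 (camera adjusted p = 0.126, or 0.477 with an estimated correlation), with 1 higher and 0 lower without Dabi-202, 2 and 0 without Dabi-204, 1 and 4 without untreated replicate 19, and 1 and 1 without Riva-313, Riva-319, sham replicate 007 or untreated replicate 17.

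Cardiac stress and fetal genes rose in 6 of 10 (9 over the list alone and 1 lower, camera adjusted p = 0.00102, or 0.477 with an estimated correlation). Xirp2 stood at 2.23 ± 0.27 and Gdf15 at 3.33 ± 0.94. Sarcomere and calcium handling genes fell in 4 of 15 (8 over the list alone and 1 higher, camera adjusted p = 0.000101, or 0.449 with an estimated correlation). The calcium release channel Ryr2 stood at -0.89 ± 0.19 and alpha myosin Myh6 at -0.98 ± 0.27. Fatty acid oxidation genes fell in 12 of 22 (18 over the list alone, camera adjusted p = 2.69e-10, or 0.449 with an estimated correlation). The carnitine palmitoyltransferase Cpt2 stood at -0.74 ± 0.13 and lipoprotein lipase Lpl at -0.76 ± 0.16. Matrix genes rose in 7 of 16 (11 over the list alone, camera adjusted p = 0.000125, or 0.449 with an estimated correlation). Fibronectin Fn1 stood at 2.64 ± 0.29 and periostin Postn at 2.12 ± 0.46. Heat shock genes rose in 7 of 12 (9 over the list alone and 1 lower, camera adjusted p = 0.00112, or 0.477 with an estimated correlation). Hspa1b stood at 2.91 ± 0.73 and the endoplasmic reticulum chaperone Hspa5 at 1.56 ± 0.35. Coagulation genes had 7 higher and 1 lower of 20 (camera adjusted p = 0.0176, or 0.477 with an estimated correlation): the urokinase gene Plau rose by 2.87 ± 0.29, the protease-activated receptor 2 gene F2rl1 by 1.81 ± 0.44 and the endothelial protein C receptor Procr by 1.45 ± 0.39, while F2r fell by 0.69 ± 0.19. Clock genes fell in 4 of 12 (5 over the list alone, camera adjusted p = 0.00258, or 0.449 with an estimated correlation). Per1 stood at -2.16 ± 0.47 and Per2 at -1.87 ± 0.42. The count was 662 without Dabi-202 and 4927 without untreated replicate 17. Cardiac stress counts were given above. Heat shock genes had 0 called by limma without Dabi-202, and 2 higher and 1 lower without untreated replicate 17. Matrix genes had 2 called without Dabi-204, and clock genes 2 without Dabi-202 and 0 without untreated replicate 19. Sarcomere genes had 1 lower without Dabi-202, Dabi-204 or untreated replicate 19, 2 without sham replicates 006 or 007 or any single aPC or rivaroxaban replicate, and 8 without untreated replicate 17. Coagulation genes had 3 higher without Dabi-202 and 4 without untreated replicate 19 or any single sham replicate. For fatty acid oxidation genes 4 and 2 were called without Dabi-202 and Dabi-204, and 2 without untreated replicate 19. Of the 42 genes named for this comparison as called, 27 were called without Dabi-202. Library weights left 125 genes, and a fit of only these groups gave 170.

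Activated protein C against untreated asks what this anticoagulant protease changed. Immediate-early genes were lower (11 of 19 called) and resident macrophage markers higher (9 of 15) at camera's preset correlation, while 0 lists passed with an estimated correlation. Without aPC-791 and aPC-792 the immediate-early count was 5 and 2. Arc fell by 4.29 ± 0.81 (adjusted p = 0.00905), Inhbb by 4.24 ± 0.41, Sphk1 by 3.67 ± 0.76, the interleukin 18 receptor subunit Il18rap by 3.54 ± 0.88, Adamts4 by 3.29 ± 0.36 and Vsig2 by 3.23 ± 0.30. The largest rises were in Derl3 (3.86 ± 0.90), Aif1, a macrophage gene (3.24 ± 0.42), Pkhd1l1 (3.17 ± 0.55), Spon2 (3.15 ± 0.70), Clec12a (3.15 ± 0.43) and the phosphatidylserine receptor Timd4 of resident macrophages (3.10 ± 0.48). Egr1 fell by 1.83 ± 0.38 (adjusted p = 0.0132). Il6 stood at -1.68 ± 0.76 (adjusted p = 0.139), Il1b at 0.01 ± 0.45 (adjusted p = 0.985) and S100a8 at -0.73 ± 0.55 (adjusted p = 0.356). Of 2384 called genes, 1007 were higher and 1377 lower, with 4903 at an unadjusted p under 0.05.

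Resident macrophage markers rose in 9 of 15 (11 over the list alone, camera adjusted p = 8.77e-07, or 0.696 with an estimated correlation). Cbr2 stood at 2.68 ± 0.19, Vsig4 at 2.69 ± 0.31 and the complement genes C1qa and C1qc at 1.48 ± 0.18 and 1.28 ± 0.15. Immediate-early genes fell in 11 of 19 (14 over the list alone, camera adjusted p = 5.5e-08, or 0.727 with an estimated correlation). Dusp1 stood at -1.50 ± 0.25 and Zfp36 at -1.77 ± 0.34. Nuclear factor kappa B targets fell in 5 of 16 (5 over the list alone, camera adjusted p = 0.000933, or 0.727 with an estimated correlation). Birc3 stood at -1.30 ± 0.16 and Nfkbia at -1.64 ± 0.23. Of the neutrophil markers 2 of 14 fell (2 over the list alone, camera adjusted p = 0.00294, or 0.727 with an estimated correlation), and Il1r2 was at -2.57 ± 0.70. Chemokines had 3 higher and 2 lower of 13, with Ccl12 at 1.72 ± 0.40 and Cxcl2 at -2.75 ± 0.49, a median of 0.56 and a mean of -0.26 (camera upward, adjusted p = 0.934). Endothelial markers had 3 higher and 6 lower of 13, with Emcn at 1.01 ± 0.16 and Robo4 at -1.39 ± 0.20 (3 and 7 over the list alone, camera adjusted p = 0.152). Oxidative phosphorylation genes had 0 of 19 called by limma over all genes and 11 higher over the list alone (camera adjusted p = 0.000106, or 0.727 with an estimated correlation). The median fold change of that list was 0.39. Plaur fell by 2.62 ± 0.37 and Plau rose by 1.06 ± 0.29. Both the spread between the untreated libraries (SD 0.792) and the share of Gm42418 in the aPC libraries moved with these groups, and fold changes fell with gene length (Spearman -0.204 across genes, which are not independent). The count was 895 and 239 without aPC-791 and aPC-792, 5235 without untreated replicate 17, and 1561 and 1566 without Riva-313 and Riva-319. Immediate-early genes had 5 and 2 called without aPC-791 and aPC-792, and neutrophil markers 0 without aPC-792, 1 without sham replicate 003 and 4 without untreated replicate 17. Nuclear factor kappa B targets had 2 called without aPC-792 and 8 without untreated replicate 19. Chemokines had 1 higher and 2 lower without aPC-791 and 1 and 0 without aPC-792, where endothelial markers had 1 and 3. Oxidative phosphorylation genes had 2 called without Dabi-202 or Dabi-204 and 7 without untreated replicate 19. Of the 28 genes named for this comparison as called, 17 were called without aPC-792. Library weights left 234 genes, and a fit of only these groups gave 3.

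**Figure D2:**
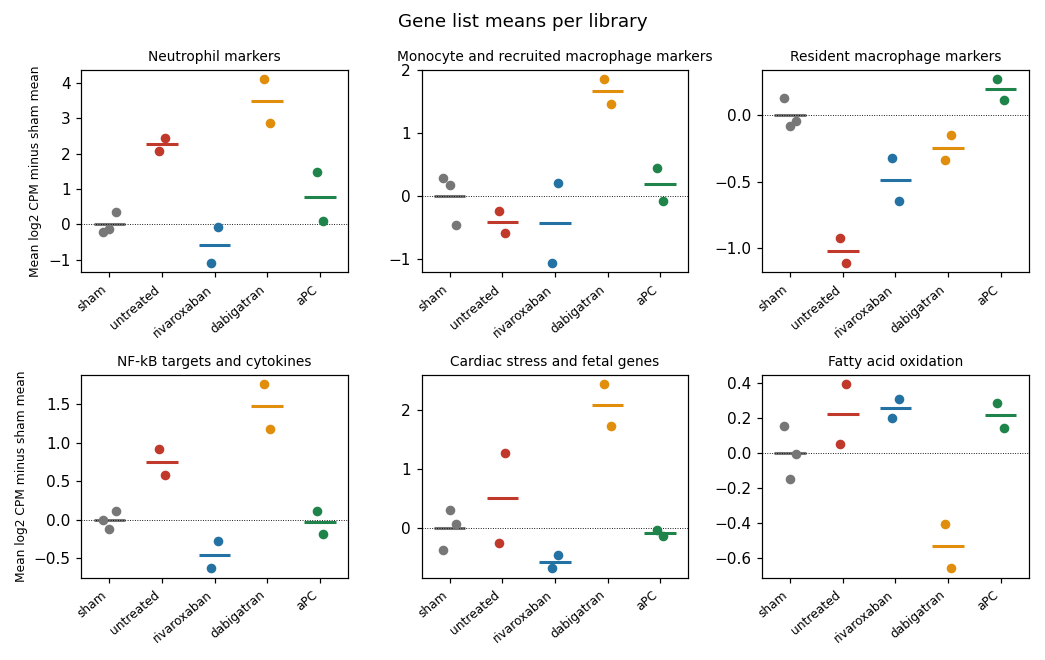
Each point is 1 library's mean log2 CPM over the tested members of a gene list, minus the mean of the 3 sham libraries, and each bar is the group mean (n = 3 for sham, 2 for the others). Dabigatran libraries lie highest for neutrophil markers and cardiac stress genes and lowest for fatty acid oxidation genes.

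The direct comparison of rivaroxaban with dabigatran bears on the subject of the series' title, a difference between factor Xa and factor IIa inhibitors in the inflammation of the injured heart. Lower with rivaroxaban were 12 of 14 neutrophil markers, 12 of 16 nuclear factor kappa B targets and 9 of 10 cardiac stress genes, and higher were 19 of 22 fatty acid oxidation genes. The lists passed at camera's preset correlation and by fry, while 0 passed with an estimated correlation, and 8, 6 and 10 fatty acid oxidation genes were called without Riva-313, Riva-319 and Dabi-204 and 6 nuclear factor kappa B targets without Dabi-202. S100a8, on mm10 chromosome 3 from 90668978 to 90670035, was at 1.97 ± 0.85 (SD, n = 2) with rivaroxaban and 7.20 ± 0.83 (SD, n = 2) with dabigatran, a difference of -5.22 ± 0.55 (adjusted p = 0.000469). Cxcl3 was lower by -5.57 ± 0.67 (adjusted p = 0.00066), the stress-induced hormone gene Gdf15 by -5.49 ± 0.94, S100a9 by -5.31 ± 0.57, the neutrophil chemokine receptor Cxcr2 by -5.18 ± 0.74 and the interleukin 1 receptor antagonist Il1rn by -5.16 ± 0.47. Il6 differed by -4.60 ± 0.76 (adjusted p = 0.00271), Il1b by -4.39 ± 0.45 (adjusted p = 0.000423), Tnf by -3.08 ± 0.56 (adjusted p = 0.0042), Nppa by -2.52 ± 0.37 (adjusted p = 0.00167) and the brain natriuretic peptide Nppb by -4.41 ± 1.07 (adjusted p = 0.0155). Higher with rivaroxaban were Inmt (3.29 ± 0.61), Clec18a (3.00 ± 0.64), Lvrn (2.76 ± 0.44), Lgals4 (2.68 ± 0.34) and the potassium channel subunit Kcnv2 (2.63 ± 0.40).

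Of 14 neutrophil markers, 12 were lower with rivaroxaban (13 over the list alone, camera adjusted p = 1.66e-09, or 0.354 with an estimated correlation). Mmp9 stood at -4.58 ± 0.37 and Csf3r at -4.20 ± 0.42. Monocyte markers were lower in 9 of 14 (11 over the list alone, camera adjusted p = 1.21e-05, or 0.407 with an estimated correlation). Versican Vcan stood at -1.95 ± 0.16 and Ccr2 at -1.93 ± 0.34. Nuclear factor kappa B targets were lower in 12 of 16 (12 over the list alone, camera adjusted p = 1.4e-07, or 0.354 with an estimated correlation). Sele stood at -3.29 ± 0.32, the inflammasome sensor Nlrp3 at -3.41 ± 0.38 and cyclooxygenase 2 (Ptgs2) at -3.68 ± 0.54. Chemokines were lower in 8 of 13 (9 over the list alone and 1 higher, camera adjusted p = 7.5e-05, or 0.354 with an estimated correlation). Ccl7 stood at -3.75 ± 0.29 and Cxcl2 at -4.45 ± 0.49. Cardiac stress genes were lower in 9 of 10 (9 over the list alone and 1 higher, camera adjusted p = 6.29e-06, or 0.392 with an estimated correlation). Xirp2 stood at -2.42 ± 0.27 and Ankrd1 at -2.01 ± 0.30. Inflammasome and cell death genes were lower in 6 of 11 and higher in 1 (6 and 1 over the list alone, camera adjusted p = 0.00303, or 0.392 with an estimated correlation). The necroptosis kinase Ripk3 stood at -1.77 ± 0.24. Without Dabi-202, 6 nuclear factor kappa B targets and 3 inflammasome genes were called lower. Without Riva-313, 5 monocyte markers and 3 inflammasome genes were called lower.

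Fatty acid oxidation genes were higher with rivaroxaban in 19 of 22 (20 over the list alone, camera adjusted p = 2.25e-10, or 0.354 with an estimated correlation). Cpt2 stood at 1.21 ± 0.13, Hadha at 0.78 ± 0.13 and Etfdh at 0.74 ± 0.13. Cardiac ion channels were higher in 9 of 17 and lower in 1 (10 and 1 over the list alone, camera adjusted p = 0.000436, or 0.407 with an estimated correlation). Kcnj3 stood at 1.47 ± 0.32 and Kcnd2 at 1.43 ± 0.32. Coagulation and fibrinolysis genes were lower in 8 of 20 (8 over the list alone, camera adjusted p = 0.000431, or 0.354 with an estimated correlation). Plaur stood at -3.67 ± 0.37, Plau at -2.36 ± 0.29, Procr at -1.78 ± 0.39 and thrombomodulin Thbd at -1.03 ± 0.33. Heat shock genes were lower in 6 of 12 (9 over the list alone, camera adjusted p = 7.5e-05, or 0.414 with an estimated correlation). Hspb1 stood at -2.96 ± 0.36. Glycolysis and hypoxia genes were lower in 9 of 16 and higher in 2 (10 and 2 over the list alone, camera adjusted p = 0.00549, or 0.414 with an estimated correlation). Enolase Eno1 stood at -1.26 ± 0.14 and the glucose transporter Slc2a1 at -1.90 ± 0.23. In total 3161 genes differed, 1271 higher and 1890 lower with rivaroxaban, with 4984 at an unadjusted p under 0.05. The higher share was 40.2%, and it was 53.9% with libraries centred on their median and 50.1% after quantile normalization. The count was 919 and 1334 without Riva-313 and Riva-319, 939 without Dabi-202, and 4839 and 4840 without untreated replicates 17 and 19. Of the fatty acid oxidation genes 8 and 6 were called without Riva-313 and Riva-319 and 10 without Dabi-204. Cardiac ion channels had 1 higher without Dabi-202 or Riva-313 and 4 without Riva-319. Glycolysis genes had 3, 3 and 4 lower without Dabi-202, Riva-313 and Riva-319, and coagulation genes 5 lower without Dabi-202. A fit without both untreated libraries left these fold changes as they were and gave 4842 genes.

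**Figure D3:**
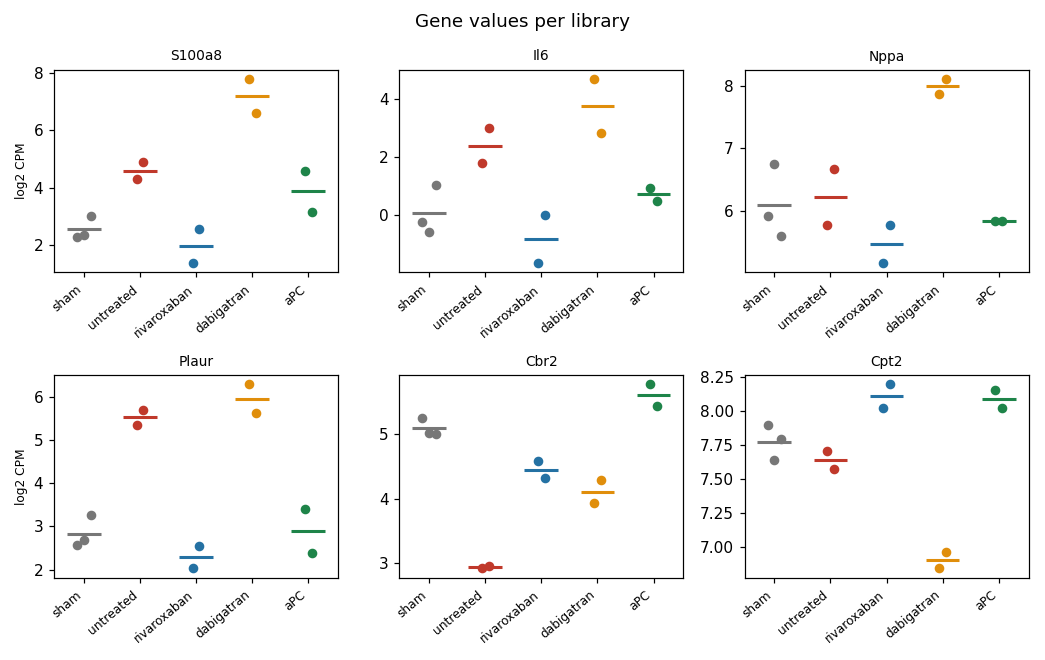
Log2 CPM of 6 genes in each of the 11 libraries, by group, with a bar at the group mean. S100a8 lies at a mean of 7.20 with dabigatran and 1.97 with rivaroxaban, and Cpt2 at 6.90 and 8.11.

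A comparison of aPC with rivaroxaban asks whether these treatments differed. Few genes were called, and most of those were lower with aPC, by a margin that depended on the fit. Gnb1l was higher by 2.53 ± 0.28 (adjusted p = 0.00384), at 10.16 ± 0.02 (SD, n = 2) with aPC and 7.63 ± 0.27 (SD, n = 2) with rivaroxaban. Il1rn was higher by 2.29 ± 0.47 (adjusted p = 0.0439), Ccl7 by 1.54 ± 0.29, the antisense transcript Foxo6os by 1.51 ± 0.31, the glycogen-targeting gene Ppp1r3c by 1.45 ± 0.26 and Cbr2 by 1.16 ± 0.19. Lower were the potassium channel Kcnt1 (-3.25 ± 0.43), the olfactory receptor gene Olfr78 (-2.80 ± 0.37), Vsig2 (-2.56 ± 0.30), Atp8b5 (-2.50 ± 0.43), Lgals4 (-2.50 ± 0.34) and the mucin gene Muc6 (-2.48 ± 0.42). Smooth muscle and pericyte markers fell in 3 of 10, Myh11 at -1.82 ± 0.25, Notch3 at -1.28 ± 0.19 and Mylk at -0.87 ± 0.14 (6 over the list alone, camera adjusted p = 9.59e-05, or 0.555 with an estimated correlation), and 1 of these passed after a trend over GC content and length was removed. Resident macrophage markers were higher in 4 of 15, among them C1qa at 0.91 ± 0.18 and C1qb at 0.85 ± 0.17 (8 over the list alone, camera adjusted p = 4.19e-06, or 0.555 with an estimated correlation), and 0 passed after that removal. Of the 17 genes named for this comparison as called, 3 and 0 were called without aPC-791 and aPC-792, 4 and 0 without Riva-313 and Riva-319, and 8 without sham replicate 006. Without aPC-791, aPC-792, Riva-313 or Riva-319, 0 smooth muscle markers and 0 resident macrophage markers passed. Resident macrophage markers had 1 and 0 called without sham replicates 003 and 006, and smooth muscle markers 5 without untreated replicates 17 or 19.

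Oxidative phosphorylation genes had 0 of 19 called over all genes and 15 higher over the list alone (camera adjusted p = 3.8e-09, or 0.6 with an estimated correlation). Cox5a stood at 0.53 ± 0.14 (adjusted p = 0.0894) and Ndufs1 at 0.48 ± 0.13 (adjusted p = 0.092). Neutrophil markers had 0 of 14 called and 5 higher over the list alone (camera adjusted p = 0.00021, or 0.692 with an estimated correlation). S100a9 stood at 2.33 ± 0.57 (adjusted p = 0.0787) and S100a8 at 1.90 ± 0.55 (adjusted p = 0.114). In total 208 genes differed by limma, 28 higher and 180 lower with aPC, with 2836 at an unadjusted p under 0.05. Beside this stands that Gm42418 held 6.78% and 6.73% of the aPC reads, and that fold changes fell with gene length (Spearman -0.245 across genes, which are not independent). The genes called lower had a median length of 4221 bases against 3380 for all. The count was 14 and 12 without aPC-791 and aPC-792, 11 and 1 without Riva-313 and Riva-319, 1186 and 1202 without untreated replicates 17 and 19, and 75, 43 and 85 without sham replicates 003, 006 and 007. Without untreated replicates 17 or 19, 6 oxidative phosphorylation genes and 1 neutrophil marker were called. The number of genes was 101 with the GC and length trend removed, 117 by voom, 1197 in a fit without the untreated libraries, 1947 in a fit of only these groups, and 3219 with library weights. The share that was higher was 13.5% of the 208 and 28.7%, 40% and 47% in those last fits.

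Activated protein C against dabigatran sets the protease beside the thrombin inhibitor. Neutrophil markers (10 of 14 called), immediate-early genes (16 of 19) and cardiac stress genes (8 of 10) were lower with aPC, and oxidative phosphorylation genes (19 of 19) and fatty acid oxidation genes (18 of 22) higher. These lists passed at camera's preset correlation, and 0 lists with an estimated correlation. Without aPC-791, aPC-792 and Dabi-202, immediate-early genes had 6, 6 and 4 called. Without aPC-792 or Dabi-202, 5 neutrophil markers and 4 cardiac stress genes were called, and oxidative phosphorylation genes had 3, 5 and 6 without aPC-791, aPC-792 and Dabi-204. Il1r2 fell by 4.32 ± 0.70 (adjusted p = 0.00321), the inducible chaperone Hspa1b by 4.18 ± 0.73, the gelatinase Mmp9 by 4.01 ± 0.37, Csf3r by 3.97 ± 0.42 and Rab44 by 3.87 ± 0.67. Large rises were in the acyl-CoA synthetase Acsm5 (2.51 ± 0.36), Armc2 (2.46 ± 0.53), Gnb1l (2.39 ± 0.28), Inmt (2.22 ± 0.61) and Ubxn10 (2.18 ± 0.52). S100a8 was lower by -3.33 ± 0.55 (adjusted p = 0.00366), Il6 by -3.06 ± 0.76 (adjusted p = 0.0187), Nppa by -2.15 ± 0.37 (adjusted p = 0.00429), Procr by -1.98 ± 0.39 (adjusted p = 0.00741) and Egr1 by -1.56 ± 0.38 (adjusted p = 0.0179).

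Every tested oxidative phosphorylation gene, 19 of 19, was higher with aPC (19 over the list alone, camera adjusted p = 1.7e-11, or 0.375 with an estimated correlation). Ndufs1 stood at 0.75 ± 0.13 and succinate dehydrogenase Sdha at 0.65 ± 0.13. Fatty acid oxidation genes were higher in 18 of 22 (19 over the list alone, camera adjusted p = 1.65e-12, or 0.375 with an estimated correlation). Cpt2 stood at 1.19 ± 0.13 and Acads at 0.92 ± 0.13. Sarcomere and calcium handling genes were higher in 6 of 15 (9 over the list alone, camera adjusted p = 4.92e-05, or 0.375 with an estimated correlation). The calcium pump Atp2a2 stood at 0.92 ± 0.20 and cardiac troponin Tnni3 at 0.83 ± 0.20. Immediate-early genes were lower in 16 of 19 (17 over the list alone, camera adjusted p = 1.05e-07, or 0.375 with an estimated correlation). Egr2 stood at -3.33 ± 0.40 and Fosl1 at -2.53 ± 0.31. Neutrophil markers were lower in 10 of 14 (10 over the list alone, camera adjusted p = 1.79e-06, or 0.375 with an estimated correlation) and nuclear factor kappa B targets in 11 of 16 (13 over the list alone, camera adjusted p = 7.25e-07, or 0.375 with an estimated correlation). Nlrp3 stood at -2.74 ± 0.38 and Il1b at -2.71 ± 0.45. Cardiac stress genes were lower in 8 of 10 (9 over the list alone, camera adjusted p = 1.79e-05, or 0.375 with an estimated correlation). Filamin C (Flnc) stood at -3.11 ± 0.40. Fibroblast markers were higher in 4 of 10 (4 over the list alone, camera adjusted p = 0.0258, or 0.375 with an estimated correlation). Decorin Dcn stood at 0.82 ± 0.16. In total 2913 genes were called, 1247 higher and 1666 lower, with 4860 at an unadjusted p under 0.05. The higher share was 42.8%, and it was 60.6% with libraries centred on their median, 53.5% after quantile normalization and 32.4% with the 20 most abundant genes removed. Gm42418, at 6.78% and 6.73% of reads in aPC and at 2.09% and 0.997% in dabigatran, is among those 20. The count was 1249 and 871 without aPC-791 and aPC-792, 1160 without Dabi-202, and 4703 and 4714 without untreated replicates 17 and 19. Fold changes fell with gene length (Spearman -0.0902), with medians of 2653 and 3469 bases among genes called higher and lower. With the GC and length trend removed, 2644 of the 2913 stayed called. Sarcomere genes had 1 called without either aPC replicate, 2 without either dabigatran replicate and 3 without either rivaroxaban replicate, and fibroblast markers 2 without either aPC replicate. Nuclear factor kappa B targets had 5 called without aPC-792 or Dabi-202 and 7 without aPC-791. A fit without both untreated libraries, with these folds unchanged, gave 4710 genes.

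Rivaroxaban against sham asks how far the treated and operated hearts stood from sham surgery. No gene passed: limma called 0 of 13541, with 761 genes (5.62%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.237. The genes with the smallest p were Rtn4r (-2.52 ± 0.34, adjusted p = 0.237), Vcan (-0.93 ± 0.14, adjusted p = 0.243), Col11a2 (-1.55 ± 0.25, adjusted p = 0.243), the fatty acid transporter Slc27a1 (0.85 ± 0.14, adjusted p = 0.243), Ano10 (1.00 ± 0.18, adjusted p = 0.37) and the enkephalin precursor Penk (1.61 ± 0.30, adjusted p = 0.37). S100a8 stood at -0.58 ± 0.50, Il6 at -0.91 ± 0.69 and Nppa at -0.62 ± 0.34, with adjusted p from 0.958 to 0.999. Resident macrophage markers had 0 of 15 called and a median of -0.45 (camera adjusted p = 4.02e-09, or 0.35 with an estimated correlation), and Cbr2 stood at -0.64 ± 0.17 (adjusted p = 0.588). Fatty acid oxidation genes had 0 of 22 called and a median of 0.17 (camera adjusted p = 4.04e-06, or 0.704 with an estimated correlation). Chemokines had 0 of 13 called over all genes and 2 lower over the list alone (camera adjusted p = 0.000127, or 0.475 with an estimated correlation). Ccl7 stood at -1.39 ± 0.26 (adjusted p = 0.397). Voom also called 0 genes, library weights called 198, and every fit that left out 1 library called 0. The libraries of a gene did not overlap in 32.4% of genes, where chance gives 20%.

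Dabigatran against sham asks the same of the thrombin inhibitor. Neutrophil genes led the rises: Il1r2 at 5.04 ± 0.64 (adjusted p = 0.00141), Cxcr2 at 4.69 ± 0.67, S100a8 at 4.65 ± 0.50, Mmp9 at 4.43 ± 0.34 and S100a9 at 4.39 ± 0.52, followed by Gdf15 at 4.34 ± 0.86. Large falls were in Tmem82 (-2.28 ± 0.54), Card14 (-2.24 ± 0.42), the sodium channel subunit Scn4b (-2.09 ± 0.47), Hmcn2 (-2.08 ± 0.25) and Papln (-2.04 ± 0.56). Il6 rose by 3.69 ± 0.69 (adjusted p = 0.00694), Il1b by 3.08 ± 0.41 (adjusted p = 0.0016), Tnf by 2.20 ± 0.51 (adjusted p = 0.0169), Nppa by 1.90 ± 0.34 (adjusted p = 0.00571) and Procr by 2.15 ± 0.36 (adjusted p = 0.00421). Myh6 fell by 0.83 ± 0.25 (adjusted p = 0.0422).

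Neutrophil markers rose in 12 of 14 (12 over the list alone, camera adjusted p = 8e-10, or 0.286 with an estimated correlation) and monocyte markers in 9 of 14 (9 over the list alone, camera adjusted p = 2.32e-05, or 0.423 with an estimated correlation). Arginase Arg1 stood at 3.08 ± 0.55 and Ccr2 at 2.02 ± 0.31. Nuclear factor kappa B targets rose in 10 of 16 (11 over the list alone, camera adjusted p = 1.72e-07, or 0.286 with an estimated correlation). Nlrp3 stood at 2.33 ± 0.35 and Sele at 2.02 ± 0.29. Chemokines rose in 7 of 13 (8 over the list alone and 1 lower, camera adjusted p = 0.000492, or 0.286 with an estimated correlation). Cxcl3 stood at 4.07 ± 0.61 and Ccl7 at 2.37 ± 0.26. Cardiac stress genes rose in 8 of 10 (9 over the list alone and 1 lower, camera adjusted p = 1.17e-05, or 0.339 with an estimated correlation). Xirp2 stood at 2.39 ± 0.25 and Tgfb2 at 1.72 ± 0.26. Coagulation genes rose in 8 of 20 (8 over the list alone, camera adjusted p = 0.000598, or 0.286 with an estimated correlation). Plaur stood at 3.12 ± 0.34 and annexin Anxa2 at 1.72 ± 0.24. Cardiac ion channels fell in 9 of 17 (13 over the list alone, camera adjusted p = 1.79e-06, or 0.286 with an estimated correlation). Kcnd2 stood at -1.60 ± 0.29. Fatty acid oxidation genes fell in 14 of 22 (19 over the list alone, camera adjusted p = 1.12e-08, or 0.286 with an estimated correlation). Cpt2 stood at -0.87 ± 0.12 and Acadm at -0.51 ± 0.12. In total 2508 genes were called, 1584 higher and 924 lower, with 4619 at an unadjusted p under 0.05. The higher share was 63.2%, and it was 47.8% with libraries centred on their median and 51.3% after quantile normalization. The count was 374 without Dabi-202, 1193, 1366 and 1446 without sham replicates 003, 006 and 007, and 4248 and 4260 without untreated replicates 17 and 19. Without Dabi-202 the called members were 7 for neutrophil markers, 2 for monocyte markers, 3 each for nuclear factor kappa B targets, chemokines and coagulation genes, 1 for cardiac stress genes, 1 for fatty acid oxidation genes and 0 for cardiac ion channels. Fatty acid oxidation genes had 2, 5 and 5 called without sham replicates 003, 006 and 007, 4 without Dabi-204, 7 without either rivaroxaban replicate and 9 without either aPC replicate, and cardiac ion channels 4, 3 and 5 without those sham replicates. Of the 30 genes named for this comparison as called, 16 were called without Dabi-202. A fit without both untreated libraries, with these folds unchanged, gave 4252.

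Activated protein C against sham gave few calls. Gnb1l rose by 2.08 ± 0.26 (adjusted p = 0.00793), the insulin-degrading enzyme gene Ide by 0.92 ± 0.16, the tissue factor pathway inhibitor gene Tfpi by 0.89 ± 0.17, Selenbp2 by 0.78 ± 0.14, Acy3 by 0.77 ± 0.15 and the glutathione transferase Gstm2 by 0.76 ± 0.14. The largest falls were in the death receptor gene Tnfrsf25 (-2.50 ± 0.44), Muc6 (-2.34 ± 0.38), Cmtm5 (-2.32 ± 0.30), Olfr78 (-2.29 ± 0.34), Col11a2 (-2.23 ± 0.25) and Kcnt1 (-2.19 ± 0.39). Smooth muscle and pericyte markers fell in 3 of 10, with Notch3 at -1.38 ± 0.17, Myh11 at -1.68 ± 0.23 and Mylk at -0.88 ± 0.12 (7 over the list alone, camera adjusted p = 6.16e-06, or 0.541 with an estimated correlation), and 1 passed after the GC and length trend was removed. Oxidative phosphorylation genes had 0 of 19 called over all genes and 13 higher over the list alone (camera adjusted p = 1.15e-08, or 0.767 with an estimated correlation). Immediate-early genes had 0 of 19 called and 6 lower over the list alone (camera adjusted p = 1.9e-06, or 0.767 with an estimated correlation). S100a8 stood at 1.32 ± 0.50 (adjusted p = 0.234), Il6 at 0.64 ± 0.69 (adjusted p = 0.682) and Nppa at -0.25 ± 0.34 (adjusted p = 0.754). Of the 15 genes named for this comparison as called, 0 were called without either aPC replicate, 5, 3 and 1 without sham replicates 003, 006 and 007, and 7 without either rivaroxaban replicate. Smooth muscle markers had 0 called without either aPC replicate or sham replicate 007, 1 without sham replicates 003 or 006, and 5 without untreated replicates 17 or 19. Immediate-early genes had 1 called without sham replicate 006 and 2 without untreated replicates 17 or 19.

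In total 159 genes differed between aPC and sham, 17 higher and 142 lower, with 2307 at an unadjusted p under 0.05. Fold changes fell with gene length (Spearman -0.26) and with GC content (-0.213) across genes, which are not independent, and the genes called lower had a median length of 4760 bases. Gm42418, at 6.78% and 6.73% of the aPC reads, lay between 1.57% and 1.77% in sham. The count was 1 and 5 without aPC-791 and aPC-792, 19, 22 and 10 without sham replicates 003, 006 and 007, 42 without either Riva-313 or Riva-319, and 779 and 776 without untreated replicates 17 and 19. The number of genes was 47 with the GC and length trend removed, 80 by voom, 778 in a fit without the untreated libraries, 813 in a fit of only these groups and 1784 with library weights.

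The injury score asks how far each heart lay along the contrast of the 4 other groups with sham. Its signature held 4 genes: 1700030N03Rik was higher (1.21 ± 0.14), and Col11a2 (-1.54 ± 0.18), Rtn4r (-1.91 ± 0.25) and Mhrt, a long noncoding RNA antisense to the beta myosin gene (-1.27 ± 0.16), were lower. The mean score was -0.369 ± 0.247 in sham (SD, n = 3), 2.75 ± 0.274 in untreated, 1.64 ± 0.429 in rivaroxaban, 3.17 ± 0.25 in dabigatran and 2.08 ± 0.436 in aPC hearts (SD, n = 2 each). Rivaroxaban differed from untreated by -1.11, dabigatran by 0.418 and aPC by -0.677, and rivaroxaban differed from dabigatran by -1.53. The sign for dabigatran turned in other settings, to -0.164 with the 100 genes of smallest p per direction and to as low as -1.5 with a library left out (untreated replicate 17), and that for aPC turned to 0.521 with the stricter filter. Each difference of the main setting had an exact permutation p of 0.333, the smallest that 2 against 2 libraries allow, and this does not hold for the other settings. The signature was chosen on these same libraries, so its distance from sham is not independent evidence.

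The covariance of fold changes against untreated was 0.385 for rivaroxaban and aPC, 0.264 for dabigatran and aPC, and 0.17 for rivaroxaban and dabigatran. Its SD over single libraries was 0.262, 0.223 and 0.248. Simulated unchanged groups that share the untreated libraries gave 0.0472, 0.0473 and 0.0473. These take the same spread for every group, below that of the untreated pair (SD 0.792). They and the simulated correlation of 0.5 are thus too low. Those observed were 0.755, 0.507 and 0.342 across genes, which are not independent. Rivaroxaban and aPC shared 301 genes higher and 399 genes lower than untreated, with 1 called in opposite directions. Dabigatran and aPC shared 267 and 292 with 50 in opposite directions, and rivaroxaban and dabigatran shared 137 and 115 with 66 in opposite directions. Each of these values includes the noise of the shared untreated libraries. With 1 untreated library given to each response of a pair, a division made after the data were seen, the mean covariance was 0.228 (0.24 and 0.216 for the possible ways) for rivaroxaban and aPC. It was 0.107 (0.0829 and 0.131) for dabigatran and aPC, and 0.013 (0.0492 and -0.0232) for rivaroxaban and dabigatran. The covariance with aPC was larger for rivaroxaban than for dabigatran by 0.121, the largest of the 3 splits of these 4 libraries, with 0.0595 the highest of the others, and 3 splits cannot give a share under 0.33. Without untreated replicate 17 the covariances were 0.78, 0.623 and 0.54.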

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

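Voom, the removal of a GC and length trend, the fit without the untreated libraries, the removal of the 20 most abundant genes, the division of the untreated libraries and the ontology counts were chosen after the data were seen, and the other alternatives before. Where a count below moved and neither the number of libraries nor the threshold itself explains it, the cause was not tested. No paired analysis was possible because the groups share no replicate numbers. The count tests foreseen for recovered reads (a quasi-likelihood test and one with size factors) were not run, although whole reads were recovered, and voom took their place. A library left alone in its group was assumed to vary like the other groups.

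Requiring an absolute log2 fold change of at least 1 left 846 genes between untreated and sham, 764, 1063 and 1168 for rivaroxaban, dabigatran and aPC against untreated, 1605 for rivaroxaban and 1246 for aPC against dabigatran, and 1010 for dabigatran and 91 for aPC against sham. At an adjusted p under 0.1 the counts were 2978 between untreated and sham, 2430, 3093 and 4065 for rivaroxaban, dabigatran and aPC against untreated, 610 for aPC against rivaroxaban and 403 for aPC against sham.

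Library weights gave 25 genes between untreated and sham and 37, 125 and 234 for rivaroxaban, dabigatran and aPC against untreated. They gave 3219 for aPC against rivaroxaban, and 198 and 1784 for rivaroxaban and aPC against sham. A fit of only the 2 groups compared gave 471 between untreated and sham, 0, 170 and 3 for rivaroxaban, dabigatran and aPC against untreated, 1947 for aPC against rivaroxaban and 813 for aPC against sham. The 0 is limma's count, beside 2287 genes at an unadjusted p under 0.05. Voom gave 117 genes for aPC against rivaroxaban and 80 for aPC against sham, and removing the GC and length trend gave 101 and 47. A fit without the untreated libraries, which pools the spread of the closer pairs, gave 4842 for rivaroxaban and 4710 for aPC against dabigatran, 1197 for aPC against rivaroxaban, and 4252 and 778 for dabigatran and aPC against sham.

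With each library left out in turn the counts ran from 261 to 5197 between untreated and sham, from 43 to 5029, 662 to 4927 and 239 to 5235 for rivaroxaban, dabigatran and aPC against untreated, from 919 to 4840 for rivaroxaban against dabigatran, from 1 to 1202 for aPC against rivaroxaban, from 871 to 4714 for aPC against dabigatran, and from 374 to 4260 and 1 to 779 for dabigatran and aPC against sham. Rivaroxaban against sham stayed at 0 in each. The highest counts came without an untreated library, 17 or 19. The lowest came without sham replicate 006 for 261, Riva-313 for 43 and 919, Dabi-202 for 662 and 374, aPC-792 for 239 and 871, Riva-319 for the 1 of aPC against rivaroxaban, and aPC-791 for the 1 of aPC against sham.

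Camera with an estimated correlation called 0 lists in each of the 10 comparisons. Fry called 1 list between untreated and sham, 0 for rivaroxaban and 1 for aPC against untreated, 2 for aPC against rivaroxaban, and 0 and 2 for rivaroxaban and aPC against sham, beside 12 for dabigatran against untreated, 16 for rivaroxaban and 16 for aPC against dabigatran, and 12 for dabigatran against sham. Leaving out libraries, camera called 6 to 14 lists between untreated and sham, 7 to 15, 9 to 18 and 4 to 9 for rivaroxaban, dabigatran and aPC against untreated, 6 to 12 for aPC against rivaroxaban, and 7 to 16 and 4 to 11 for rivaroxaban and aPC against sham.

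The difference of the injury score between dabigatran and untreated, 0.418, was -0.00197 after quantile normalization, -0.164 with the 100 genes of smallest p per direction, and -1.5 to 0.417 with a library left out. For aPC against untreated, -0.677, it was 0.521 with the stricter filter and -4.19 to -1.16 with a library left out. For rivaroxaban against untreated, -1.11, it was -3.2 to -2.3, and for rivaroxaban against dabigatran, -1.53, it was -2.74 (without Dabi-204) to -1.01 (without Riva-313). With the 100 genes per direction the last 3 differences were -1.69, -2.47 and -2.31, so their size depends on the genes of the signature. No score could be computed without aPC-791, Dabi-202, Riva-319 or any sham library, since no signature of both directions was left. The covariances of rivaroxaban and aPC, dabigatran and aPC, and rivaroxaban and dabigatran were 1.01, 2.06 and 0.469 over only the genes of the signature, 0.228, 0.107 and 0.013 with the untreated libraries divided between the responses, and ran from 0.303 to 0.78, 0.218 to 0.623 and 0.0836 to 0.54 with a library left out.

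Of 300 gene values named in the report, 300 kept their direction and side of the threshold with robust eBayes and with no filter, 298 with median centring, 284 with quantile normalization, 280 by voom and 173 with library weights. Fits of only the 2 groups lost 103 calls. Leaving out a library, often of another group, lost 466 in 3300 values. Direction could not turn, as the libraries of called genes did not overlap. Depth limits the low genes: 3 reads lie at -2.83 log2 CPM in the deepest library.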

Other observations

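Ontology terms were tested after the lists had been seen. Hypergeometric p-values here take genes as independent and do not measure variation between mice. The removals of the GC and length trend, 20 most abundant genes and untreated libraries followed sight of the data. So did the lost calls and the look at the assignments. What each weighed explanation predicts was set out before its test. Genes named beside these terms were chosen after their values were seen. Dabigatran hearts were higher in genes of ribosome production. Of 85 tested genes of ribosome biogenesis, 49 were higher than in sham (10.3 expected by chance, adjusted p = 2.51e-20), and 52 were lower with rivaroxaban than with dabigatran (12.3 expected, adjusted p = 1.06e-19). The nucleolar genes Mybbp1a and Nop58 rose by 1.08 ± 0.14 and 1.72 ± 0.29 against sham, and the ribosomal protein gene Rpl3 by 1.24 ± 0.18. The 49 was 45 after quantile normalization, 41 with median centring, 2 without Dabi-202 and 23, 31 and 28 without sham replicates 003, 006 and 007. The 52 was 15 without Dabi-202 and 12 and 26 without Riva-313 and Riva-319.

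Mitochondrial genes by ontology term, some of them members of the fixed lists, were higher with aPC than with dabigatran. They were 154 of 328 genes of the mitochondrial inner membrane (30.7 expected, adjusted p = 3e-69), 41 of 47 of the respiratory chain (4.39 expected, adjusted p = 2.97e-33) and 23 of 26 of the tricarboxylic acid cycle (2.43 expected, adjusted p = 1.24e-18). Maob rose by 1.27 ± 0.17, Ogdhl by 0.91 ± 0.11 and isocitrate dehydrogenase Idh2 by 0.80 ± 0.14. Stress fiber genes were lower in 27 of 62 (7.76 expected, adjusted p = 3.79e-07), with nonmuscle myosin Myh9 at -1.92 ± 0.16 and Actn1 at -2.09 ± 0.20. The respiratory chain count was 6 without either aPC-791 or aPC-792 and 9 without Dabi-204, the inner membrane count 47, 38 and 76, and the acid cycle count 6, 6 and 12. The stress fiber count was 18, 14 and 18 without aPC-791, aPC-792 and Dabi-202. Collagen trimer genes were lower in untreated than in sham hearts in 23 of 55 (3.06 expected, adjusted p = 9.74e-12), with Col6a2 at -1.40 ± 0.22 and C1qtnf9 at -2.03 ± 0.34. That count was 9, 7 and 16 without sham replicates 003, 006 and 007, 13 without untreated replicate 19 and 15 without Riva-313 or Riva-319.

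The untreated libraries stood apart from all 4 other groups in 207 genes, 99 higher (among them Inhbb, Grk5 and Sgk1) and 108 lower (among them Cbr2, Csf1r, Adgre1 and Vsig4). Resident macrophage markers supplied 4 of the lower genes (0.12 expected, adjusted p = 0.000132). A GC or length trend is argued against as the whole cause, since 187 genes (90.3%) stayed called in all 4 comparisons without it. A strain or donor difference stays open: 17.9% of the genes had another within 500 kb, where 1000 random sets had a median of 16.4% and a 95th percentile of 23.2%. An injury response that the drugs lack also stays open, with 2 members of the neutrophil, nuclear factor kappa B, chemokine, acute phase and cardiac stress lists (Cxcl12 and Nfkbia, 0.978 expected, one-sided exact hypergeometric p = 0.256).

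The aPC libraries differed from the rivaroxaban libraries in 208 genes, 13.5% of them higher, against 47% of 3219 with library weights. Gene length and GC content may explain part of this: 46.2% of the genes, or 96, were still called after that trend was removed. Of the 112 no longer called, 98 had a smaller fold, with a median absolute log2 fold change of 1.15 before and 0.86 after and a standard error of 0.215 and 0.205, while 37 kept a p that would have passed before and were lost to the adjustment over all genes. A few genes taking most of the reads stay open: 92.8%, or 193, were still called with the 20 most abundant genes removed, but that rescaling moved the median absolute fold from 1.25 to 1.35, the way most of these genes already went, so it decides nothing. A biological effect of aPC stays open and was not tested apart from these.

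In the main fit no gene told rivaroxaban from sham at an adjusted p under 0.05. Camera passed 1 list higher and 10 lower at its preset correlation and 0 with an estimated one. Too few libraries stay open. The 95% interval of rivaroxaban against sham held dabigatran's fold change for 3.67% (92) of 2508 genes called with dabigatran. These were chosen for large folds, so this shows only that rivaroxaban was unlike dabigatran. Their median fold change in its direction was 0.87 with dabigatran and -0.11 with rivaroxaban. A mislabelled sample stays open: 5.62% of all genes, or 761, had an unadjusted p under 0.05, but 1373 did without the untreated libraries and 2467 with library weights, so the share depends on which libraries set the spread. That less injured tissue was sampled with rivaroxaban is not tested by these values.

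In a fit of the 5 rivaroxaban and sham libraries alone limma called 0 genes, and the highest of the other 9 splits called 2. At an unadjusted p under 0.05 the real split gave 1903 genes, the most of all 10, with 1502 the highest of the others. These 10 splits cannot give a share under 0.05.

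The contrast of the 4 other groups with sham called 4 genes, and 4 of 100 random assignments of the 11 libraries to groups of the same sizes, the real one included, called as many. The share lies under 0.05, but the drawn assignments mix the groups and had a larger spread within groups (median residual SD per gene 0.289 to 0.363, against 0.233), which lowers their calls, so it does not by itself exclude chance. The highest of the others called 1201 genes, which points to a structure of the samples. All 3 assignments with more than 4 genes set both dabigatran libraries and 1 untreated library against the rest, and these were the 3 that did so among the 99 drawn.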
